A study of Mus musculus with 9 samples.

How the data were processed

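The series holds 9 Affymetrix mouse arrays of passage 3 neurospheres from C57BL/6J embryos of embryonic day 12.5, with 3 arrays each of spinal cord spheres (SCSC), DRG spheres (rNCSC) and DRG spheres grown with BMP4 (BMP NCSC). Samples were put in groups by their titles, which also number the replicates. Per the labels' protocols, RNA was extracted with TRIzol and spin columns, and biotinylated cRNA was hybridised. The deposited values are on the log2 scale, 1 per probe set. They were made with GCRMA, per the submitters' processing notes, whose version is not given in the sources used here. GCRMA models background from probe sequence, normalizes arrays to each other and summarises each probe set, and it draws unexpressed transcripts together at low values, so differences that involve a mean under 4 have an uncertain size. It also makes the arrays' distributions alike, so a change in the total RNA of a cell would not show. The medians of the 9 arrays lay between 3.98 and 4.03.

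The table had 45101 probe sets, of which 64 were controls. In the platform annotation supplied, 34958 had 1 gene symbol, 932 had several and were left out, and 9211 were unlisted and stay unnamed here. The gene identifiers of 34754 were found in the gene table of assembly GRCm38.p6. That table was used for names and chromosomes alone, since no build is named by the labels. Each of 18194 genes was represented by the probe set with the highest mean over the 9 arrays. For 9012 genes with more than 1 probe set, others may disagree, and 15 called genes in rNCSC against BMP NCSC and 20 in SCSC against BMP NCSC had probe sets called in both directions. A gene was tested when its value reached 5 on at least 3 arrays, which left 10320 genes. A gene at the floor in rNCSC and SCSC could pass only through BMP NCSC, which fixes its direction against that group. Likewise, a gene at the floor in BMP NCSC could pass only through rNCSC or SCSC, so it could hardly be called lower in them. Counts of called members and p-values of the lists in comparisons with BMP NCSC carry both limits.

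Tests used limma 3.58.1 in R 4.3.3, with group means over all 9 arrays in 1 model, moderated variances (6 residual and 2.39 prior degrees of freedom), two-sided p and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05 and an absolute log2 difference of at least 1. Differences are the first-named group minus the second. The 26 gene lists were fixed before the data were examined, as were the grouping of samples, the 3 comparisons and the other settings tried, except those named below as added later. They cover CNS progenitor transcription factors, radial glia, oligodendrocytes, astrocytes, CNS and peripheral neurons, neural crest, Schwann cells, mesenchyme, BMP, hedgehog, Notch, Wnt and FGF responses, Hox genes, forebrain and midbrain, cell cycle, immediate early and heat shock genes, hypoxia, cholesterol, and endothelial, microglial, erythroid, melanocyte, meningeal and skeletal muscle markers. Lists with at least 5 tested members, 20 in all, were tested with camera at a preset correlation of 0.01. With an estimated correlation, the radial glia list in rNCSC against BMP NCSC was the 1 call that held. Ranges of a list's adjusted p over alternatives are all at the preset correlation.

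Named genes followed a rule fixed in advance. In each comparison it took the 12 called genes with the greatest difference each way, with non-overlapping arrays and a mean of at least 7 in the higher group. It added up to 4 members with the smallest p of each list and a fixed set of markers. Further members of a list, and genes named as exceptions to a list's direction, were chosen after their values were seen. The shared-control simulation drew 100 sets of unchanged groups. The position of rNCSC used genes called between SCSC and BMP NCSC. The rNCSC means did not enter that contrast, but the rNCSC arrays entered the filter and the variances.

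The steps were tested on simulated data for the 10320 genes, with 200 genes changed in each of 20 simulations. A gene was found there at an adjusted p below 0.05 with no size limit, so the rates are not those of the calling rule. With the same spread in the 3 groups, 82.4%, 81.0% and 82.0% of changes of 1 were recovered for rNCSC against SCSC, rNCSC against BMP NCSC and SCSC against BMP NCSC, and 96.3%, 96.1% and 96.8% of changes of 2. Of the genes found, 5.37%, 5.22% and 4.89% were false. With each group given its own spread, 77.9%, 76.3% and 76.8% of changes of 1 were recovered and the false share was 18.7%, 27.1% and 14.6%. The mean number of false genes in a simulation was 39.4, 63.6 and 29.5. These shares hold for 200 changed genes. They do not hold for the far larger numbers called against BMP NCSC or the far smaller ones for rNCSC against SCSC. The spreads used were SDs of 3 arrays, which are themselves uncertain. Calls of genes that vary in 1 group are still less secure than the adjusted p states.

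The alternatives changed the filter, the probe set rule, the scaling, the floor, the variance model, the samples in the fit, the replicate block, array weights and the threshold, and left out each array in turn. Choices added after seeing the data were leaving out X- and Y-linked genes and leaving out arrays with the genes chosen on all 9. The latter was added because the filter, applied again to 8 arrays, drops genes expressed in BMP NCSC alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.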

Results

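Gene expression was measured on 9 Affymetrix mouse arrays of passage 3 neurospheres, free-floating colonies grown from tissue of C57BL/6J mouse embryos at embryonic day 12.5. Each of 3 kinds of sphere had 3 arrays. SCSC were grown from spinal cord, in medium with 20 ng/ml bFGF and 20 ng/ml EGF. rNCSC were grown in the same medium from dorsal root ganglia (DRG), which are sensory ganglia formed by the neural crest. BMP NCSC were grown from DRG in that medium with 10 ng/ml BMP4, a bone morphogenetic protein, added. The labels do not say whether the 3 arrays of a group came from separate embryos or cultures, so the p-values measure only the spread between these arrays. Array medians lay between 3.98 and 4.03 on the log2 scale, and 38.7% to 39.9% of probe sets reached 5. The number of arrays limits the precision. Of 18194 genes with a value, 10320 were tested.

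The first comparison asked how DRG spheres grown without BMP4 differed from those grown with it. Several transcription factors and glial genes of central nervous system (CNS) progenitors were high in rNCSC and near the lower end of the scale in BMP NCSC, with exceptions such as Sox2. Fabp7, a fatty acid binding protein of radial glia, was at 14.44 ± 0.042 (SD, n = 3) in rNCSC and 3.05 ± 0.24 (n = 3) in BMP NCSC. Olig1, a transcription factor of the oligodendrocyte lineage, was at 13.57 ± 0.21 against 2.49 ± 0.16, and its relative Olig2 at 12.10 ± 0.045 against 1.47 ± 0.15 (n = 3 each). In the other direction, the cartilage gene Cnmd was at 2.78 ± 0.091 in rNCSC and 13.96 ± 0.51 in BMP NCSC, and the fibrillar collagen gene Col2a1 at 3.18 ± 0.09 and 14.17 ± 0.12 (n = 3 each). Sox2, a transcription factor of neural progenitors, was abundant in both, at 12.88 ± 0.13 and 12.55 ± 0.067 (n = 3 each), a log2 difference of 0.32 that was below the size limit.

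**Figure D1:**
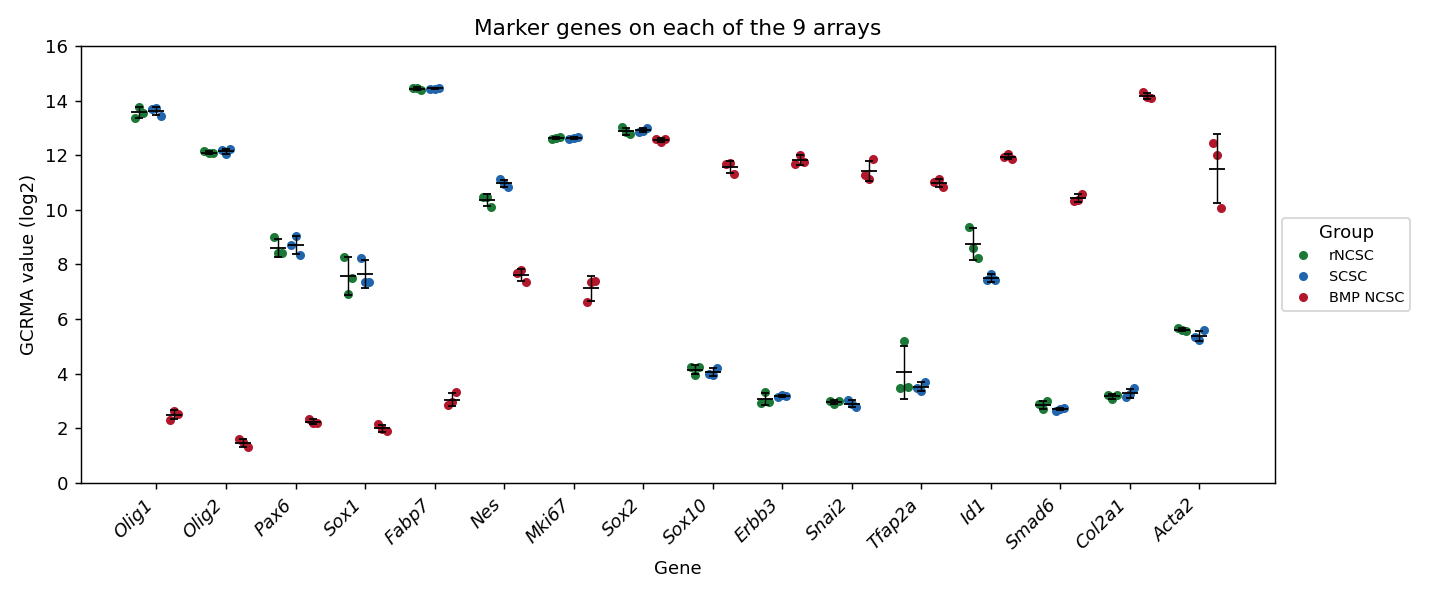
GCRMA values (log2, vertical axis) of 16 genes on each array, with points for the 3 arrays of each group, horizontal marks for the group means and bars for 1 SD (n = 3). For Olig1, Olig2, Fabp7, Sox10, Snai2 and Col2a1 the rNCSC and SCSC points lie together and far from the BMP NCSC points, whereas Sox2 lies above 12 in all 3 groups.

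Of the 17 CNS progenitor transcription factors tested, 15 were higher in rNCSC and none lower (limma camera, adjusted p = 8e-06, and adjusted p = 0.085 with an estimated correlation). They included Zic1 (log2 difference 10.12, SE 0.18), Pax6 (6.36, SE 0.20), Pou3f4 (5.65, SE 0.17) and Sox1 (5.56, SE 0.35), while Sox2 and Irx3 (-0.50) were not called. In this list Olig1, Olig2, Pax6, Sox1, Nkx2-2, Dbx2, Zic1, Zic2 and Sox21 had means under 4 in BMP NCSC. These genes could pass the filter only through rNCSC or SCSC, so a lower call was hardly possible for them. The list's count and p carry that limit. Among 20 genes of radial glia and neural stem cells, 17 were higher and none lower (adjusted p = 7.1e-06, and adjusted p = 0.039 with an estimated correlation). Ptprz1, a receptor phosphatase, differed by 7.97 (SE 0.36), the matrix protein gene Tnc by 7.40 (SE 0.14), and Nes, which encodes the intermediate filament nestin, by 2.74 (SE 0.15). Nes was nonetheless at 7.61 ± 0.23 (n = 3) in BMP NCSC. Fabp7, Prom1 and Dll3 of the radial glia list had means under 4 there, so the same limit applies to that list. In the Notch pathway 9 of 13 genes were higher and 1, the receptor Notch2, was lower (adjusted p = 0.037, and adjusted p = 0.21 with an estimated correlation). The ligand Dll1 differed by 5.68 (SE 0.29) and the feedback gene Nrarp by 5.49 (SE 0.25). This Notch call was lost without any 1 of the BMP NCSC arrays, at adjusted p of 0.086, 0.088 and 0.087 without replicates 1, 2 and 3, and ranged from 0.019 to 0.088 over the alternatives with a preset correlation. The filter was applied again to 8 arrays there, which drops genes expressed in BMP NCSC alone. The parts of the filter and of the arrays in this loss cannot be told apart.

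Oligodendrocyte lineage genes did not move as a block. Of 13 tested, 8 were higher in rNCSC, among them Sox8 (7.88, SE 0.14) and Bcas1 (4.38), and 2 were lower, namely Sox10 (-7.42, SE 0.14) and the proteoglycan gene Cspg4 (-3.62, SE 0.40). The list passed the test at an adjusted p of 0.039, with an adjusted p of 0.21 with an estimated correlation and a range of 0.019 to 0.072 over the alternatives. Sox10, which also marks the neural crest and its glia, was at 4.14 ± 0.17 in rNCSC and 11.56 ± 0.22 in BMP NCSC (n = 3 each).

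Neural crest genes were lower in rNCSC for 11 of the 17 tested and higher for 2 (adjusted p = 0.0066, and adjusted p = 0.18 with an estimated correlation). The lower ones included the neuregulin receptor gene Erbb3 (-8.73, SE 0.14) and the transcription factors Snai2 (-8.46, SE 0.18) and Tfap2a (-6.93, SE 0.40). The exceptions were the endothelin receptor gene Ednrb (7.87, SE 0.44), which radial glia also express and which stands in that list too, and the cadherin gene Cdh6 (1.57). The crest call did not hold without BMP NCSC replicate 1 (adjusted p = 0.10), replicate 2 (0.12) or replicate 3 (0.089), within a range of 0.00027 to 0.12 over the alternatives. The filter, applied again there, dropped genes expressed in BMP NCSC alone, so this loss does not show dependence on 1 array. Foxd3, at 2.97 in rNCSC and 3.70 in BMP NCSC, was under the filter. Snai2, Ngfr and Sox10 of this list lay under the filter level of 5 in rNCSC and SCSC. These genes could pass only through BMP NCSC, so their direction was fixed by passing, and the list's count and p carry that limit.

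Genes of mesenchyme, smooth muscle and extracellular matrix were lower in rNCSC for 17 of 18 tested (adjusted p = 8.3e-07, and adjusted p = 0.085 with an estimated correlation). Besides Col2a1 they included the proteoglycan genes Bgn (-10.33, SE 0.13) and Acan (-9.21, SE 0.20), the collagen gene Col3a1 (-9.53, SE 0.16) and the smooth muscle actin gene Acta2 (-5.90, SE 0.51). The phosphatase gene Alpl was higher (1.60). Cnn1, Myh11, Col1a1, Col1a2, Sp7 and Eng, also in this list, were under the filter and not tested. All 5 meningeal fibroblast genes tested were lower (adjusted p = 0.0066, and adjusted p = 0.21 with an estimated correlation), Lum and Dcn being shared with the matrix list. The list has 10 members, of which Foxc2, Aldh1a2, Crabp2, Col1a1 and Slc6a13 were under the filter. Islr, Ogn and Lum, as well as Acan of the matrix list, had means under 4 in rNCSC and SCSC. They could pass the filter only through BMP NCSC, so their direction was fixed by passing it. Genes known to respond to BMP signalling were lower for 16 of 18 (adjusted p = 1.5e-06, and adjusted p = 0.092 with an estimated correlation). Smad6, an inhibitor of the pathway, differed by -7.57 (SE 0.10), Bmp2 by -7.45 (SE 0.24), Id1 by -3.20 (SE 0.25) and Id3 by -1.48 (SE 0.15). Hey1 was higher (1.04) and Id2 not called (-0.16). Dlx2, also in this list, had means under 4 in rNCSC and SCSC, so its direction was fixed by the filter too.

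Cell cycle genes were higher in rNCSC for 23 of 24 tested (adjusted p = 2.8e-08, and adjusted p = 0.21 with an estimated correlation). Mki67, a marker of proliferating cells, was at 12.62 ± 0.036 in rNCSC and 7.12 ± 0.44 in BMP NCSC (n = 3 each), and the mitotic kinase gene Plk1 differed by 6.42 (SE 0.15). Cholesterol synthesis genes were higher for 6 of 13 and lower for none (adjusted p = 0.0066, and adjusted p = 0.34 with an estimated correlation), led by Dhcr7 (2.54, SE 0.20) and Mvd (2.46, SE 0.21). Immediate early and heat shock genes, which can also answer to handling of the cells, were lower for 9 of 13 and higher for 1, Hsph1 (adjusted p = 0.0066, and adjusted p = 0.21 with an estimated correlation). Fos differed by -4.62 (SE 0.32) and Hspb1 by -5.80 (SE 0.12). This list was no longer past the test without BMP NCSC replicate 1 (adjusted p = 0.10), 2 (0.11) or 3 (0.087), within a range of 0.00085 to 0.11 over the alternatives. As for the crest list, the filter was applied again there and may account for the loss.

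The remaining lists did not pass the test in this comparison. Astrocyte genes were higher for 6 of 14 and lower for 2 (adjusted p = 0.055; 0.035 without rNCSC replicate 2, in a range of 0.021 to 0.2 over the alternatives), and Gfap was under the filter at 3.28 in rNCSC and 3.67 in BMP NCSC. General and CNS neuron genes were higher for 6 of 11 and lower for 2 (adjusted p = 0.18). Schwann cell and peripheral glia genes were lower for 7 of 11 and higher for 3 (adjusted p = 0.12), and peripheral neuron genes were lower for 3 of 6 and higher for 2 (adjusted p = 0.54). Hox genes were lower for 5 of 21 (adjusted p = 0.25). For the hedgehog pathway, Wnt targets, FGF and ERK response and hypoxia and glycolysis, the adjusted p was 0.25, 0.85, 0.23 and 0.62. Among Wnt targets the median difference was 0.83 and the mean -1.01, since Lef1 (-7.43), Dkk1 (-6.17) and Wif1 (-4.58) lay far below the others. Of the marker lists for other tissues, microglia and macrophage, erythroid and skeletal muscle genes had no member past the filter. The endothelial list had 1, Egfl7 (-2.52), the melanocyte list 3, of which Mitf (-3.43) and Sox10 were lower, and the forebrain and midbrain list 3, of which Dlx1 (-7.54) and Dlx2 (-6.79), were lower, Dlx2 being also in the BMP response list.

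Over all genes tested, limma called 2197 higher and 2335 lower in rNCSC than in BMP NCSC. In all, 8043 genes (77.9%) had an adjusted p below the threshold at any size. The 3 arrays of one group lay wholly above those of the other for 79.6% of genes, where chance gives 10%. For 967 called genes the lower group mean was under 4, near the floor of the values, so the size of those differences depends on the background correction. The number lower dropped to 1549 without BMP NCSC replicate 2, when 9540 genes passed the filter, and 7 of 18 lists passed without BMP NCSC replicate 1, 2 or 3, in place of 11 of 20. The meningeal fibroblast list then had fewer than 5 members past the filter and was not tested.

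**Figure D2:**
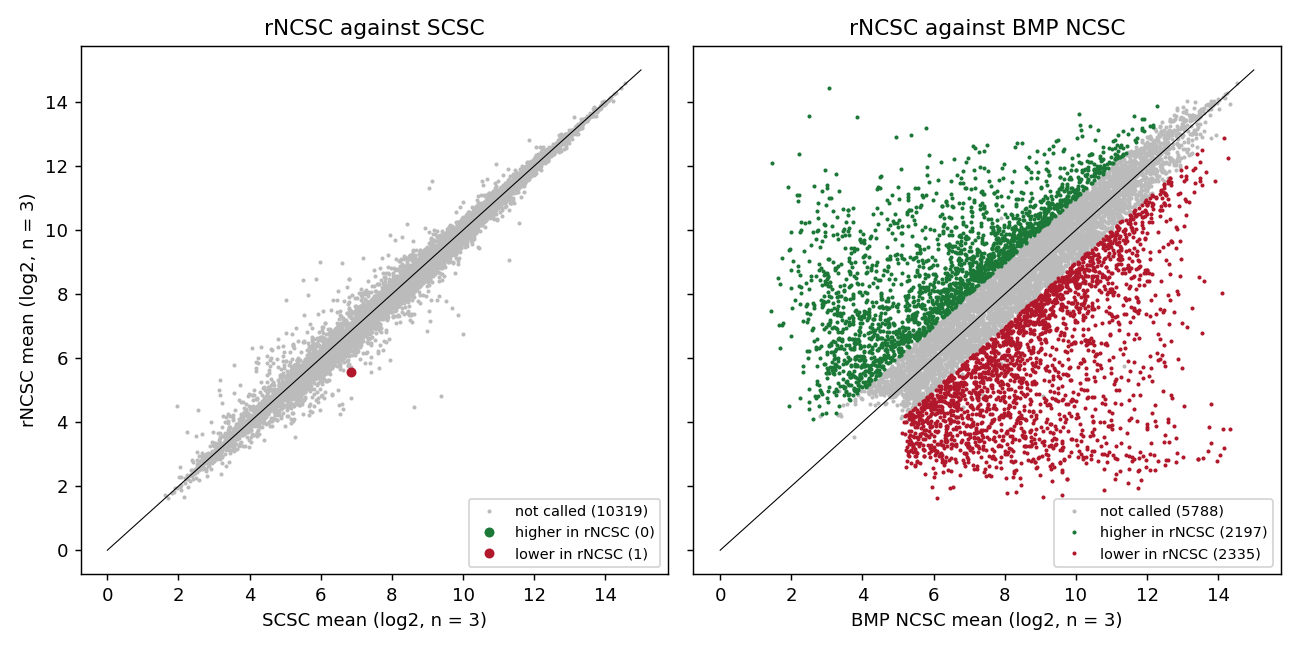
Mean log2 value of each tested gene in rNCSC (vertical axes) against SCSC (left) or BMP NCSC (right), n = 3 arrays each, with called genes in colour and the line of equal values. The left panel has 0 genes higher and 1 lower, and the right panel has 2197 higher and 2335 lower.

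The comparison of the spinal cord spheres with the BMP4-treated DRG spheres combined a difference in tissue of origin with one in BMP4. SCSC lay far above BMP NCSC for Fabp7 (11.40), Olig1 (11.13), Olig2 (10.67) and Zic1 (9.87), and far below them for Cnmd (-11.25), the opioid precursor gene Penk (-11.20) and the peptidase gene Mme (-11.08). CNS progenitor transcription factors were higher in SCSC for 15 of 17 (adjusted p = 2e-05, and adjusted p = 0.081 with an estimated correlation) and radial glia genes for 17 of 20 (adjusted p = 2e-05, and adjusted p = 0.052 with an estimated correlation). Cell cycle genes were higher for 23 of 24 (adjusted p = 5.4e-08, and adjusted p = 0.21 with an estimated correlation). Oligodendrocyte lineage genes were higher for 8 of 13, with Sox10 (-7.51) and Cspg4 (-3.60) lower (adjusted p = 0.043, and adjusted p = 0.21 with an estimated correlation). That last call had a range of 0.02 to 0.068 over the alternatives. Cholesterol synthesis genes were higher for 6 of 13, such as Dhcr7 (2.73) and Fdps (2.16) (adjusted p = 0.0068, and adjusted p = 0.35 with an estimated correlation).

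Neural crest genes were lower in SCSC for 12 of 17, with Ednrb and Cdh6 higher (adjusted p = 0.0068, and adjusted p = 0.19 with an estimated correlation). The matrix and smooth muscle list was lower for 17 of 18 (adjusted p = 5.9e-07, and adjusted p = 0.081 with an estimated correlation), and BMP response genes for 16 of 18 (adjusted p = 5.9e-07, and adjusted p = 0.081 with an estimated correlation), with Smad6 at -7.72 and Id1 at -4.44. Meningeal fibroblast genes were lower for 5 of 5 (adjusted p = 0.0063, and adjusted p = 0.21 with an estimated correlation), and immediate early and heat shock genes for 9 of 13 (adjusted p = 0.0068, and adjusted p = 0.21 with an estimated correlation). The filter was the same. Its limits given above for the CNS progenitor, radial glia, crest, matrix, BMP response and meningeal lists hold here too. Without BMP NCSC replicates 1, 2 and 3 in turn, the crest list was at adjusted p of 0.12, 0.13 and 0.11 (range over the alternatives 0.00051 to 0.13) and the immediate early list at 0.09, 0.083 and 0.061 (range 0.00095 to 0.09). The filter was applied again there too, so its part cannot be told apart from that of the arrays. Hox genes were lower for 8 of 21, or 6 when adjusted over the list alone (adjusted p = 0.047, and adjusted p = 0.46 with an estimated correlation). Hoxc4 (-3.73) and Hoxc8 (-2.90) were among them. The Hox call was lost without rNCSC replicate 1 (adjusted p = 0.05) or SCSC replicates 2 (0.069) or 3 (0.059), within a range of 0.01 to 0.11. The Notch list missed the threshold (7 of 13 higher, 2 lower, adjusted p = 0.079, range over the alternatives 0.046 to 0.17), just passing without rNCSC replicate 3 (0.05 after rounding), and the difference between the Notch results of the 2 comparisons was not tested.

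In the same comparison the lists for astrocytes, CNS neurons, Schwann cells, peripheral neurons, hedgehog, Wnt, FGF and ERK, and hypoxia had adjusted p of 0.2, 0.089, 0.089, 0.41, 0.23, 0.98, 0.36 and 0.23. Without SCSC replicate 2 the hypoxia list was at an adjusted p of 0.04, the lowest in a range up to 0.35. In all, limma called 2473 genes higher and 2366 lower in SCSC, of 8223 (79.7%) with an adjusted p below the threshold. For every other list with genes called in either comparison with BMP NCSC, the counts over all genes and adjusted over the list alone were equal.

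**Figure D3:**
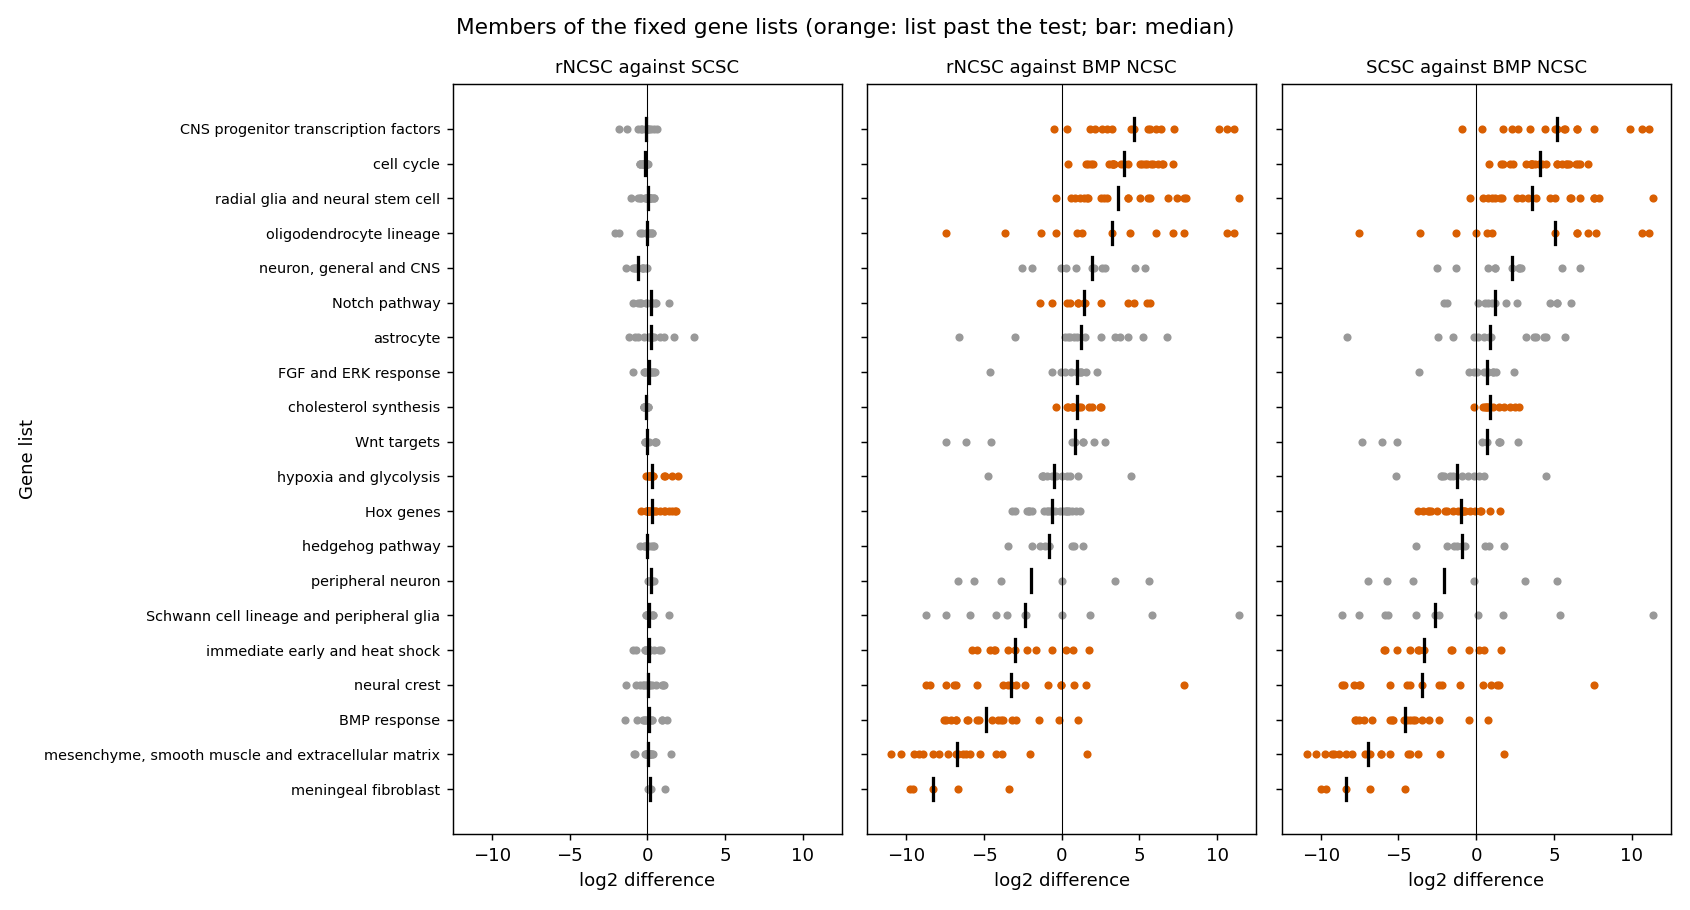
Log2 differences (horizontal axes) of the tested members of the 20 gene lists with at least 5 of them, in the 3 comparisons, with 1 point per gene, a black bar at the list's median and orange for lists past the camera test with a preset correlation. Members spread from -11.00 to 11.39 for rNCSC against BMP NCSC, but from -2.10 to 3.01 for rNCSC against SCSC.

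Spheres from DRG and from spinal cord, grown in the same medium, were set against each other directly. Several markers differed by no more than the spread of the arrays, whereas others, such as Nes and Id3, differed by more. Nes was at 10.35 ± 0.22 in rNCSC and 10.96 ± 0.13 in SCSC, and Id3 at 11.6 ± 0.25 and 10.66 ± 0.2 (n = 3 each). Neither was called. Olig2 was at 12.10 ± 0.045 in rNCSC and 12.14 ± 0.10 in SCSC, Pax6 at 8.61 ± 0.33 and 8.71 ± 0.34, Sox10 at 4.14 ± 0.17 and 4.05 ± 0.15, and Mki67 at 12.62 ± 0.036 and 12.62 ± 0.027 (n = 3 each). limma called no gene higher in rNCSC and 1 lower, Efcab7, which was named after its values were seen. It encodes a protein of the primary cilium and was at 5.58 ± 0.17 in rNCSC and 6.86 ± 0.073 in SCSC (n = 3 each, log2 difference -1.28, adjusted p = 0.0204). Efcab7 was not called without SCSC 1, when 1 other gene was lower, nor without SCSC 2, SCSC 3 or BMP NCSC 2, when 0 were. With only the 6 arrays compared, or at an adjusted p under 0.01, 0 genes were lower too; these are not all the settings tried. Unadjusted p fell under 0.05 for 1413 genes, where 516 would be expected if no gene differed, and the arrays of the groups did not overlap for 20.7% of genes, where chance gives 10%. By at least 1 on the log2 scale differed 160 genes, of which 101 had an SD over 1 within rNCSC and 11 lay on the X or Y chromosome.

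Some genes of the fixed lists had larger differences that did not pass over all genes. The myelin-associated gene Bcas1 differed by -2.10 (SE 0.24, adjusted p = 0.0754), the peripheral glial cadherin gene Cdh19 by 1.40 (SE 0.20, adjusted p = 0.101), Hey2 by 1.43 (SE 0.23, adjusted p = 0.134), Id1 by 1.24 (SE 0.25, adjusted p = 0.161) and Apoe by 3.01 (SE 0.63, adjusted p = 0.17). Adjusted over the list alone, 1 gene passed in each of the oligodendrocyte (lower), astrocyte, Schwann cell, BMP response and Notch lists (higher). No member of any list was called over all genes tested.

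Hox genes, which mark position along the body axis, were higher in rNCSC as a list, with a median difference of 0.32 over 21 genes and none called singly (adjusted p = 0.00037, and adjusted p = 0.56 with an estimated correlation). Hoxa10 (1.77, SE 0.48) and Hoxa9 (1.15, SE 0.36) were higher on each rNCSC array than on each SCSC array, whereas Hoxd10 was at 8.55 on rNCSC replicate 3 and at 2.22 to 2.67 on the other arrays of both groups. Without rNCSC replicate 3, the Hox list had an adjusted p of 0.061, the highest in a range from 3.8e-06. Hypoxia and glycolysis genes were higher too, with a median of 0.31 over 12 genes and none called (adjusted p = 0.011, and adjusted p = 0.64 with an estimated correlation), as for Ankrd37 (2.01, SE 0.58) and Vegfa (1.14, SE 0.52). That call was lost without rNCSC replicates 1 (adjusted p = 0.21) or 2 (0.051), or SCSC replicates 1 (0.1) or 3 (0.11), and ranged from 1.3e-10 to 0.21. The astrocyte and Schwann cell lists each had an adjusted p of 0.056 and passed in 12 and 10 of 19 alternatives, over ranges of 0.0051 to 0.16 and 0.0064 to 0.17. The astrocyte list passed without rNCSC 3 (0.027), SCSC 2 (0.02) or BMP NCSC 1 (0.026), 2 (0.034) or 3 (0.016), and the Schwann cell list without rNCSC 1 (0.027), SCSC 1 (0.034) or BMP NCSC 1 (0.026), 2 (0.034) or 3 (0.032). The other lists had an adjusted p between 0.098 and 0.95. Among them the Notch list, at 0.21, passed without rNCSC 3 (0.03) or SCSC 2 (0.034), in a range of 0.03 to 0.51. The cell cycle list, at 0.2, passed in 2 alternatives (range 0.023 to 0.33) and the BMP response list, at 0.098, in 1 (range 0.042 to 0.2). In place of 2 lists, 1 passed without rNCSC 2 or SCSC 3, and 4 without SCSC 2 or any 1 BMP NCSC array, the filter being applied again each time.

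**Figure D4:**
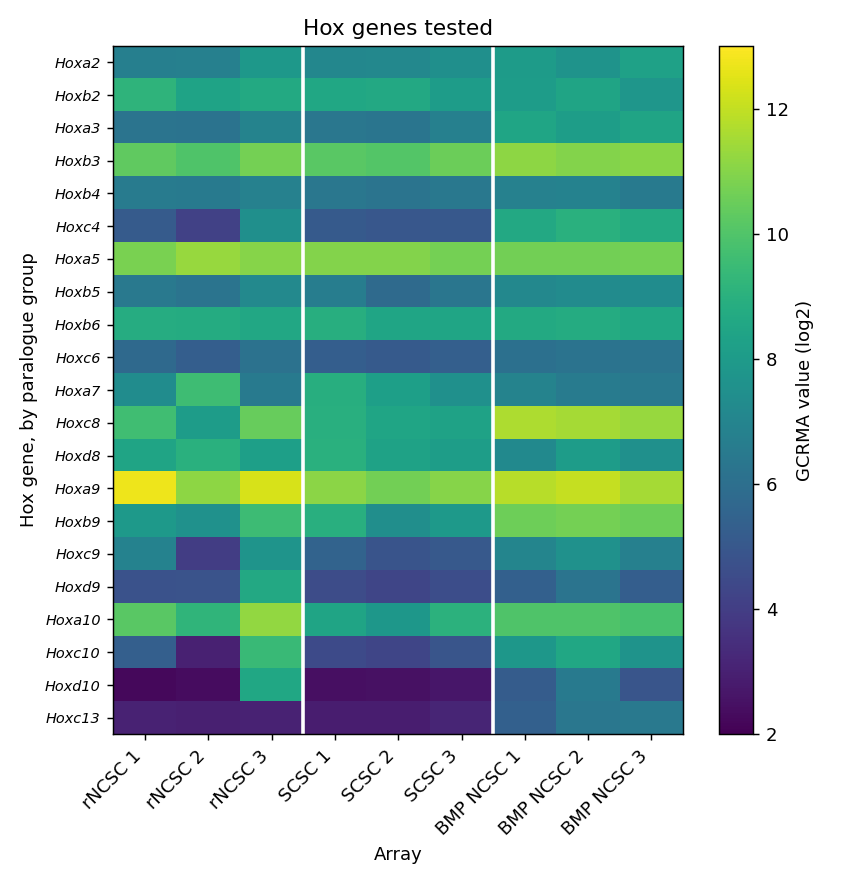
GCRMA values (log2, colour scale) of the 21 Hox genes tested, ordered by paralogue group from top to bottom, on each of the 9 arrays, with white lines between the groups. Hoxd10, Hoxc10 and Hoxd9 stand at 8.55, 9.47 and 8.63 on rNCSC 3, above the other 2 rNCSC arrays.

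The number of genes that separated rNCSC from SCSC changed most without rNCSC 2, when 18 genes were higher and 53 lower. Without rNCSC 1 the counts were 0 and 2, without rNCSC 3 they were 1 and 3, and without BMP NCSC 3 they were 1 and 1. No gene was lower without SCSC 2, SCSC 3 or BMP NCSC 2. The spread was wider in rNCSC, where 267 genes had an SD over 1, against 19 in SCSC and 150 in BMP NCSC. Simulations that gave each group its own spread used an adjusted p below 0.05 with no size limit. There limma recovered 77.9% of genes changed by 1 on the log2 scale between rNCSC and SCSC. Of the genes found, 18.7% were false. Each simulation had 200 changed genes, so this share is not that of the counts above.

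The comparisons with BMP NCSC were set beside each other to see how many of the spinal cord differences the DRG spheres shared. Of 4839 genes called between SCSC and BMP NCSC, 4300 (88.9%) were called in the same direction between rNCSC and BMP NCSC, 2120 higher and 2180 lower, and 0 were called in opposite directions. Independent lists of these sizes would share 1062. Simulated unchanged groups, both set against the same simulated BMP NCSC arrays, shared 0.01 genes on average. Groups drawn without any difference give almost no called genes to share, so this count is no baseline for the 4300. The log2 differences correlated across genes with r = 0.99, against 0.501 in the simulation, and had a covariance of 4.83 against 0.0245; genes are not independent replicates. With 3 BMP NCSC arrays the shared arrays could not be split, and part of the excess of shared genes over independent lists may come from them. For the covariance, shared arrays alone gave only the simulated 0.0245.

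On a scale from 0 at the BMP NCSC mean to 1 at the SCSC mean, rNCSC lay at a median of 0.954 over those 4839 genes. The rNCSC arrays 1, 2 and 3 lay at 0.967, 0.98 and 0.924 (SD 0.029), and the SCSC arrays, whose mean sets the scale and whose values chose the genes, at 1.009, 0.998 and 0.994. For genes higher in SCSC the median was 0.922, and for genes lower in SCSC it was 0.987, although 530 of the latter had an SCSC mean under 4, where the floor holds values together. Only 56 genes (1.16%) lay nearer to BMP NCSC than to SCSC. In a principal component analysis of the tested genes, component 1 held 93.3% of the variance and set BMP NCSC (147 to 153) apart from the other 6 arrays (-78.6 to -64.6). Component 2, with 2.54%, set rNCSC 3 at 44.8 and the other 8 arrays between -15.7 and 7.1.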

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

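Leaving out X- and Y-linked genes, and leaving out arrays with the genes chosen on all 9, were tests chosen after the results were seen; the others were planned. No called list, and no called gene among those named by the rule, changed direction under the alternatives run for it; the direction of the other called genes was not followed. Over the settings other than leaving out arrays, counts against BMP NCSC left the range of 1.5 times in these cases. Testing probe sets singly gave 3798 higher and 3734 lower for rNCSC against BMP NCSC and 4222 and 3828 for SCSC against BMP NCSC, because 17658 probe sets were tested. With no limit on size the counts were 4250 and 3793, and 4446 and 3777, and 7621 genes were shared. With an estimated correlation in camera, 1, 0 and 0 lists passed for rNCSC against BMP NCSC, rNCSC against SCSC and SCSC against BMP NCSC. The position of rNCSC lay between 0.935 and 0.975 in the 18 alternatives run for it, which did not include the variance models, the block, array weights, 6 arrays or single probe sets.

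For rNCSC against SCSC, 1 gene was higher and 3 lower with a filter at 7, 1 and 3 with trended, robust variances, and 9 and 5 with array weights. Lower genes numbered 0 at an adjusted p under 0.01 and 0 with only the 6 arrays compared, so Efcab7 was not called in either. Lists past the test numbered 4 with a filter at 7, 4 with the mean of probe sets, 6 without _x_at and _s_at probe sets, 4 with centred arrays and 5 with only the 6 arrays compared. The cause of these changes was not tested. Without X- and Y-linked genes, chosen after seeing the data, the counts were 0 and 1.

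Leaving out arrays in turn gave 0 to 18 higher and 0 to 53 lower genes and 1 to 4 lists for rNCSC against SCSC, with both maxima of genes without rNCSC 2. Without SCSC 1 the 1 lower gene was not Efcab7. For rNCSC against BMP NCSC it gave 7 to 12 lists and 1549 to 2411 lower genes. The 3 lowest counts, 1549, 1583 and 1594, came without a BMP NCSC array, when 9540 to 9545 genes passed the filter, since genes expressed in BMP NCSC alone then reached 5 on only 2 arrays. After these counts were seen, the arrays were left out again with the genes chosen on all 9, and the lower genes then numbered 2284 to 2410; lists were not run that way.

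The replicate numbers are shared by the groups, but same-numbered arrays of rNCSC and SCSC deviated with correlations of 0.04, 0.3 and 0.16, and the labels do not state that the numbers pair the samples. The replicate block gave 0 higher and 0 lower genes for rNCSC against SCSC, so Efcab7 was not called, 2199 and 2334 for rNCSC against BMP NCSC and 2477 and 2364 for SCSC against BMP NCSC. The oligodendrocyte list then had an adjusted p of 0.072 and 0.068 against BMP NCSC. As a hint from the data, 3 of 3 rNCSC arrays deviated most like their own number in SCSC, 3 of 3 in BMP NCSC, and 2 of 3 SCSC arrays in BMP NCSC. Signal near the floor limits the size of differences for 967 and 987 called genes against BMP NCSC.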

Other observations

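Tests chosen after the result was seen were those of cartilage genes, mixed-in cells, Hox position, sex-linked genes and carried-over spinal cord cells; those of the whole array, of rNCSC 2, of other probe sets and of other splits were written before their values were seen. Some cartilage genes were high in BMP NCSC. Besides Cnmd and Col2a1, a list of 21 cartilage genes that left these out had 12 tested members, of which 8 were lower in rNCSC than in BMP NCSC and none higher, with a median difference of -5.63 (limma camera p = 0.00015, and p = 0.084 with an estimated correlation). Of the 8 lower genes, Acan, Col11a2, Matn4, Hapln1 and Fmod lay under 4 on every rNCSC and SCSC array. Col9a1 reached 5 there only on rNCSC 3 (5.51). These genes passed the filter only through BMP NCSC, so their direction was fixed by passing it and the camera p carries that limit. Col11a1 and Scrg1 reached 5 on each rNCSC array and were free of it. Over all 21 members, 9 of them under the filter, the median was -1.38. Acan is also in the matrix list. Col9a1 was at 13.81 ± 0.18 in BMP NCSC and 4.58 ± 0.82 in rNCSC, and Fmod at 12.11 ± 0.81 and 3.34 ± 0.12 (n = 3 each). Sox9, a transcription factor of cartilage that neural progenitors share, was at 7.96 ± 0.24 in BMP NCSC and 8.73 ± 0.45 in rNCSC (n = 3 each). Matn1 (2.68) and Col9a2 (3.71) were at the floor in BMP NCSC. The hypothesis that a cartilage gene programme was active in BMP NCSC as a group therefore rests on a subset of its genes.

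Of 7 inhibitors of cyclin-dependent kinases, a list chosen after values were seen and not tested as a group, 2 were lower in rNCSC than in BMP NCSC, 2 higher and 3 not called. Cdkn2b was at 10.28 ± 0.26 in BMP NCSC and 5.68 ± 0.83 in rNCSC, and Cdkn1a at 12.54 ± 0.26 and 10.28 ± 0.68, whereas Cdkn2c was at 7.08 ± 0.34 and 10.44 ± 0.26 and Cdkn1c at 4.42 ± 0.15 and 6.60 ± 1.9 (n = 3 each). Those not called were Cdkn1b (0.50), Cdkn2d (0.94) and Cdkn2a (-0.62).

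The rNCSC arrays lay near the SCSC level, with 0.00969% of tested genes called between them. Spinal cord cells carried into the DRG cultures and grown out by passage 3 may account for this, and so may a conversion of DRG cells, which the sample labels name. The low rate is the observation that prompted the question and tests neither, and without rNCSC 2 the counts were 18 higher and 53 lower. These arrays hold no mark of lineage, so the 2 cannot be told apart.

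Array rNCSC 3 stood apart, with 90 genes at least 2 log2 above the median of the other 5 rNCSC and SCSC arrays, against 0 to 9 for each of those, and 65 at least 2 log2 below, against 27 for rNCSC 1 and 2 to 7 for the others. For the raised genes, cells of the BMP NCSC kind mixed into this array are argued against, and the lowered genes were not tested. Of the 90 genes, 43.3% lay over 1 log2 above the BMP NCSC mean, which a mixture cannot give, and for the 41 at or below it the implied share of 21.2% would put 67 transcripts abundant in BMP NCSC at a median of 9.79, where 3.13 was measured (SD 1.2). A fault of the whole array cannot be told apart from other causes, because 83.5% of genes lay within 0.5 log2 of the other arrays, between the bounds set beforehand. A more caudal origin of the cells may be involved but cannot be told apart from other causes, because caudal Hox genes on this array prompted the test, clustered genes are not independent and the labels give no axial level: 8 Hox genes of groups 9 to 13 deviated by a mean of 2.85 (SD 2.02) and 13 of groups 1 to 8 by 0.49 (SD 1.02, permutation p = 0.0015, two-sided).

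Array rNCSC 2 correlated more with SCSC 2 (r = 0.9929 across genes) than with rNCSC 1 (0.9863) or rNCSC 3 (0.968). In the 100 genes that best separated the other 2 rNCSC arrays from SCSC, its median position was 0.2 on a scale from 0 at SCSC to 1 at those arrays. SCSC arrays left out of the choice in the same way lay at 0.04, 0.29 and 0.35, and rNCSC 1 and 3 at 0.77 and 0.56. A mislabelled SCSC array is consistent with these positions, with 23 of the 100 genes nearer to rNCSC against 11, 28 and 34 for the left-out SCSC arrays. The Y-linked genes Kdm5d, Uty and Eif2s3y lay at 1.43 to 2.03 on rNCSC 2 but at 5.42 or more on each SCSC array. Xist was high on rNCSC 2 (12.19) and SCSC 2 (11.75) and low on the other rNCSC and SCSC arrays. These values do not settle the matter, since sex can differ between cultures of the same kind. A mislabelled array and a culture closer to SCSC for a biological reason, which was not tested, both stay open.

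Between arrays of rNCSC, 20 genes were at 7 or above on 1 array and at 4 or below on another, against 1 in SCSC and 0 in BMP NCSC. Of the 8 with another measurable probe set, 62.5% changed by at least 2 log2 the same way there. On the X or Y chromosome lay 25% of the 20. Xist, expressed from the inactive X chromosome, was at 12.19 on rNCSC 2, 11.75 on SCSC 2 and 10.67 to 11.68 on the BMP NCSC arrays, but at 2.37 to 2.67 on the other 4. On rNCSC 1 the Y-linked genes Kdm5d and Uty were at 8.77 and 8.64 and Eif2s3y at 1.82. On rNCSC 2 these 3 were at 2.03, 1.43 and 2.01, and on rNCSC 3 at 8.73, 8.43 and 10.6. They lay between 5.42 and 10.02 on the SCSC arrays and between 5.82 and 9.97 on the BMP NCSC arrays. Xist and the Y-linked transcripts were thus opposed on rNCSC 2 and rNCSC 3, which argues against 1 shared embryo for these arrays. On each BMP NCSC array and on SCSC 2, Xist and the Y-linked transcripts were measured together, which argues against cells of only 1 sex on these arrays. The sex of the cells was not balanced between the groups. Rps4l was at 2.96 and 2.97 on rNCSC 1 and 3 and between 6.35 and 8.78 on the other arrays.

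With 10 splits of 6 arrays into 3 and 3, the splits are too few for a share under 0.05. The real split called 1 gene for rNCSC against SCSC, 4532 for rNCSC against BMP NCSC and 4839 for SCSC against BMP NCSC, and the highest of the other splits called 0 in each. In the comparisons with BMP NCSC, the other splits put the large differences between groups into the spread. Few or no calls were bound to follow there, so these counts lend no support.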
